A study of Mus musculus with 18 samples.

How the data were processed

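RNA was measured in leukemic spleens of C57BL/6 mice that carried T-cell acute lymphoblastic leukemia (T-ALL) with a conditional allele of Acly. Per the labels' protocols, the leukemia cells were injected into irradiated recipient mice. Acute mice were treated once overtly leukemic and their spleens were collected 48 h later. Survival mice were treated 48 h after the transplant and their spleens were collected at the humane endpoint. The treatment was tamoxifen, which induces deletion of a conditional allele, at 3 mg per mouse in corn oil, or corn oil alone. The knockout (KO) libraries therefore differ from the wild-type (WT) libraries in tamoxifen as well as in Acly. Per the same protocols, spleens were pressed through a filter, red blood cells were lysed, and strand-specific libraries were made from total RNA.

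The 18 libraries fell into 5 groups by their titles: KO acute (n = 4), WT acute (n = 4), KO survival first wave (n = 3), KO survival second wave (n = 3) and WT survival (n = 4). The labels do not say what set the waves apart. They also do not say that the libraries of a group came from separate mice, so the p-values measure the spread between these samples, or that all mice were injected with the same primary T-ALL, so a KO and WT difference can include one between leukemias. The series design text gives 5 samples per genotype, but 10 KO and 8 WT samples are listed, and the listed samples were used.

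The authors deposited a table of gene values for the acute libraries and another for the survival libraries, in the unit signal: gene read counts estimated with kallisto 0.44.0 and divided by the size factors of DESeq, on GRCm38, per the submitters' processing notes. The DESeq version, the transcript annotation, the filter on genes, the strand setting and the exons removed by the conditional allele are not given in the sources used here. The tables were normalized separately, so tests were made within a table and levels were not compared across tables. There were 18329 genes in the acute table and 18953 genes in the survival table, and every symbol was found in the GENCODE M21 annotation of GRCm38, from which coordinates, transcript lengths and GC contents were taken.

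The smallest steps between low values gave an estimate of 6.1 to 12.7 M reads per library. Between 37.9% and 63.6% of the values under 8 were whole multiples of the step within 0.02, so whole reads were not recovered and count models were not used. The normalized totals were 7.07 to 10.39 M per library. The estimated depth sets the counting error only, and the errors given are SDs between libraries or SEs of the model.

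Values were transformed to log2(value + 1), and genes with a mean of at least 10 over a table's libraries were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend). Fold changes are on that scale, which understates the change of low genes. The p-values were adjusted with Benjamini-Hochberg over the genes tested, with a threshold of 0.05. The acute fit held the 8 acute libraries. The survival fit held all 10 survival libraries, which shared 1 estimate of the spread, and gave 4 contrasts: each wave against WT, the second wave against the first, and the mean of both waves against WT. The Acly values were also tested with exact two-sided permutation tests.

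Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 31 lists, and again with an estimated correlation. The lists held 9 to 42 genes of metabolism, growth, stress and signalling, or markers of cell types that a leukemic spleen can hold, and a list was tested with at least 5 measured members. The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. By that rule the text names Acly, and in each comparison the 6 genes with the highest and the 6 with the lowest log2 fold change among those past the threshold. These had no overlap between the groups, a mean of at least 100 in the higher group, and no predicted-gene, pseudogene, immunoglobulin or T-cell receptor segment symbol. The rule adds the 3 members with the smallest adjusted p of each list past the threshold. Other genes named in the text were chosen after their values were seen, and each is marked as such. Some genes that the rule picks are not reported here.

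The tests were checked on simulated data: negative binomial counts drawn from each gene's mean and a dispersion fitted to the mean, with randomly chosen genes changed by known folds. In the acute design (14173 genes) the test recovered 25% of genes changed 1.5-fold, 60% of those changed 2-fold and 91.5% of those changed 4-fold. In the first-wave design (14288 genes) it recovered 8.16%, 30% and 83.7%, and in the second-wave design (14314 genes) 10.2%, 30.6% and 81.3%. In the comparison of the waves (14247 genes) it recovered 6.12%, 36.2% and 77.6%, and in that of both waves with WT (14284 genes) 14%, 50% and 87.5%. The simulated genes were independent and no simulated library stood apart, so these shares may be too high for the real libraries.

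Alternatives were other pseudocounts, other filters on low values, median-centring, quantile normalization, eBayes without a trend or with robust variances, only the groups compared in the fit, and each library left out in turn. Those added after the data were seen were the removal of each library's trend with transcript length, GC content and abundance, the acute fit without 2 KO libraries of high mitochondrial share, and the survival fit without 2 WT libraries that stood apart. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.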

Results

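Gene expression was measured by RNA sequencing in 18 libraries of leukemic mouse spleens. In 10 of them Acly had been deleted in the T-ALL cells by tamoxifen (KO), and 8 came from vehicle-treated controls (WT). Acute libraries (4 KO and 4 WT) were taken 48 h after treatment of overtly leukemic mice. Survival libraries came from mice treated 48 h after transplant and followed to the humane endpoint, and their KO samples were labelled as a first wave (n = 3) and a second wave (n = 3) beside 4 WT samples. Depth was estimated at 6.1 to 8.7 M reads per KO acute library and 6.8 to 9.4 M per WT acute library. The estimates were 7.9 to 10.7 M in the first wave, 8.0 to 12 M in the second wave and 7.9 to 12.7 M in the WT survival libraries.

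Acly encodes ATP citrate lyase, the cytosolic enzyme that makes acetyl-CoA from citrate, and lies on chromosome 11 from 100476353 to 100528000 on the minus strand of GRCm38. In the acute libraries Acly fell to 58.4% of WT, from 1256 ± 122 (SD, n = 4) to 733 ± 85.1 (SD, n = 4) normalized counts, with no overlap (KO 619.6 to 803.8, WT 1128.8 to 1421.6). The log2 fold change was -0.78 (SE 0.13, limma adjusted p = 0.00266). In the survival libraries the mean was 1697 ± 154 (SD, n = 4) in WT, 727 ± 71.8 (SD, n = 3) in the first wave and 576 ± 75.3 (SD, n = 3) in the second. These were 42.8% and 34.0% of WT. Acly fell in the second wave (log2 fold change -1.56, adjusted p = 0.00155), and in the first wave its value of -1.22 missed the threshold (adjusted p = 0.0562) although every KO library was below every WT library. In exact two-sided permutation tests each of these KO and WT differences had p = 0.0286, the smallest p these designs allow. The waves differed by -0.34 (SE 0.18, adjusted p = 0.860, exact permutation p = 0.1, the smallest that 3 against 3 allows). With 1 library left out, the adjusted p of the first-wave value ranged from 0.0255 without second-wave replicate 3, where it passed, to 0.595 without first-wave replicate 1. Which exons the allele removes is not given in the sources used here, so transcripts of the deleted allele are not told apart from intact ones.

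**Figure D1:**
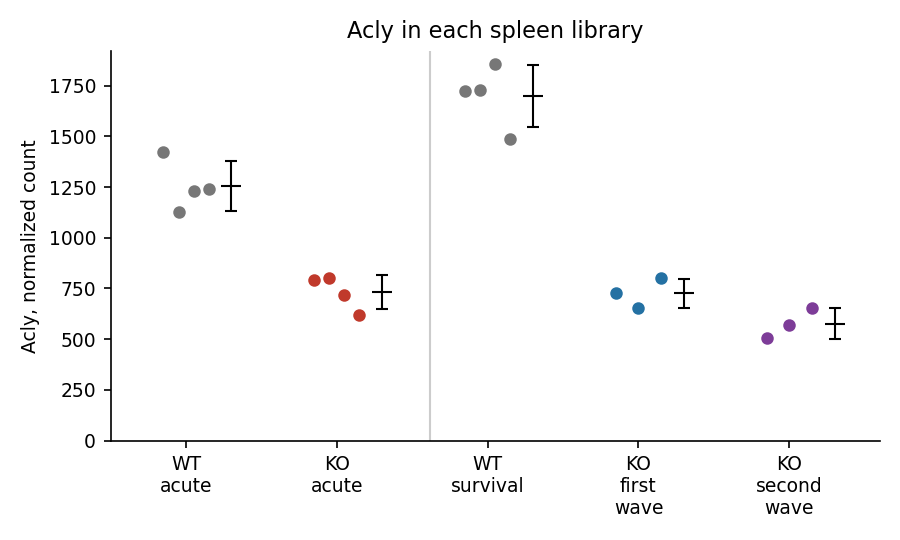
Normalized counts of Acly in each library (points) with the group mean and SD (bars), by group; the acute and survival tables, parted by the grey line, were normalized separately. Every KO library lies below every WT library of its own table, with acute KO values of 619.6 to 803.8 against 1128.8 to 1421.6 in WT.

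The acute comparison asks what changed within 48 h of deleting Acly in established leukemia. Some genes of energy metabolism fell. Of 42 measured genes of oxidative phosphorylation, the mitochondrial production of ATP, 13 fell and 0 rose, and 20 fell and 0 rose when adjusted over the list alone. Among them, Atp5b, Atp5c1 and Atp5o, which encode subunits of ATP synthase, fell from 3490 ± 479 to 1747 ± 99.6, from 1845 ± 76.7 to 929 ± 146 and from 785.0 ± 72.9 to 302.0 ± 98.8 normalized counts (SD, n = 4 each), with log2 fold changes of -0.99 (SE 0.11) for Atp5b and -1.43 (SE 0.21) for Atp5o. The list median was -0.49 (camera adjusted p = 1.85e-07, and adjusted p = 0.262 with an estimated correlation). Of 19 genes of glycolysis, the breakdown of glucose to pyruvate, 8 fell and 0 rose, and 10 fell and 1 rose when adjusted over the list alone. Ldha, lactate dehydrogenase, changed by -0.77 (SE 0.12), Pgk1, phosphoglycerate kinase, by -0.81 (SE 0.14), and Eno1, enolase, by -0.97 (SE 0.17), with a list median of -0.49 (adjusted p = 0.000289, and adjusted p = 0.131 with an estimated correlation).

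The tricarboxylic acid (TCA) cycle and the supply of acetyl-CoA showed lower values as well. Of 21 TCA cycle genes 4 fell and 1 rose (5 and 1 when adjusted over the list alone), with a median of -0.29 (adjusted p = 0.0119, and adjusted p = 0.425 with an estimated correlation). Idh3a, a subunit of isocitrate dehydrogenase, changed by -0.98 (SE 0.13), Ogdh, of oxoglutarate dehydrogenase, by -1.08 (SE 0.16), and Sdhb, of succinate dehydrogenase, by -1.20 (SE 0.23). Of 18 genes of acetyl-CoA supply 6 fell and 0 rose (9 and 0 when adjusted over the list alone), with a median of -0.42 (adjusted p = 0.00481, and adjusted p = 0.391 with an estimated correlation). Besides Acly these included Mpc1, a subunit of the mitochondrial pyruvate carrier, at -1.06 (SE 0.18), and Dld, dihydrolipoamide dehydrogenase, at -0.67 (SE 0.16; with the trend over length, GC content and abundance removed -0.44, adjusted p = 0.0739). Acly is the targeted gene, so its fall was set by the design. It is part of the count, median and test of the acetyl-CoA supply list, which was not tested without it. The TCA cycle call was lost without the 2 KO libraries of high mitochondrial share (adjusted p = 0.0810) and with the trend over length, GC content and abundance removed (adjusted p = 0.0797). The TCA cycle list lay at percentile 4.99 of random lists matched on these properties.

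Some genes of the cell cycle and of protein folding in the endoplasmic reticulum fell. Of 27 genes of G2 and mitosis 7 fell and 0 rose, over all genes and when adjusted over the list alone (median -0.27, adjusted p = 0.000289, and adjusted p = 0.537 with an estimated correlation). Ccnb1, a cyclin of mitotic entry, fell from 2466 ± 369 (SD, n = 4) to 1248 ± 300 (SD, n = 4) normalized counts, Ccna2, another, changed by -0.92 (SE 0.16), and Nusap1, a spindle protein, by -0.84 (SE 0.15). Of 26 S phase genes 6 fell and 0 rose (10 and 1 when adjusted over the list alone), with a median of -0.23 (adjusted p = 0.00367, and adjusted p = 0.574 with an estimated correlation). Pcna, the sliding clamp of DNA polymerase, changed by -0.78 (SE 0.13), and Rrm2 and Rrm1, subunits of ribonucleotide reductase, by -0.67 (SE 0.12) and -0.62 (SE 0.13). Of 19 genes of the unfolded protein response 7 fell and 0 rose (8 and 0 when adjusted over the list alone), with a median of -0.30 (adjusted p = 0.00117, and adjusted p = 0.262 with an estimated correlation). Pdia3, a disulfide isomerase, changed by -0.99 (SE 0.15), Calr, calreticulin, by -0.68 (SE 0.14), and Sdf2l1, of a chaperone complex, by -1.45 (SE 0.28). The S phase call was lost without WT acute replicate 1 (median -0.14, adjusted p = 0.0827), after quantile normalization (-0.11, adjusted p = 0.107) and with the trend over length, GC content and abundance removed (-0.09, adjusted p = 0.132). With that trend removed Pcna was at -0.36 (adjusted p = 0.0603), Rrm2 at -0.35 (0.106) and Rrm1 at -0.39 (0.0916), and Rrm1 also missed the threshold after quantile normalization (0.0702). The G2 and mitosis, S phase and unfolded protein response medians lay at percentiles 8.3, 10.81 and 3.54 of random lists matched on length, GC content and abundance.

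**Figure D2:**
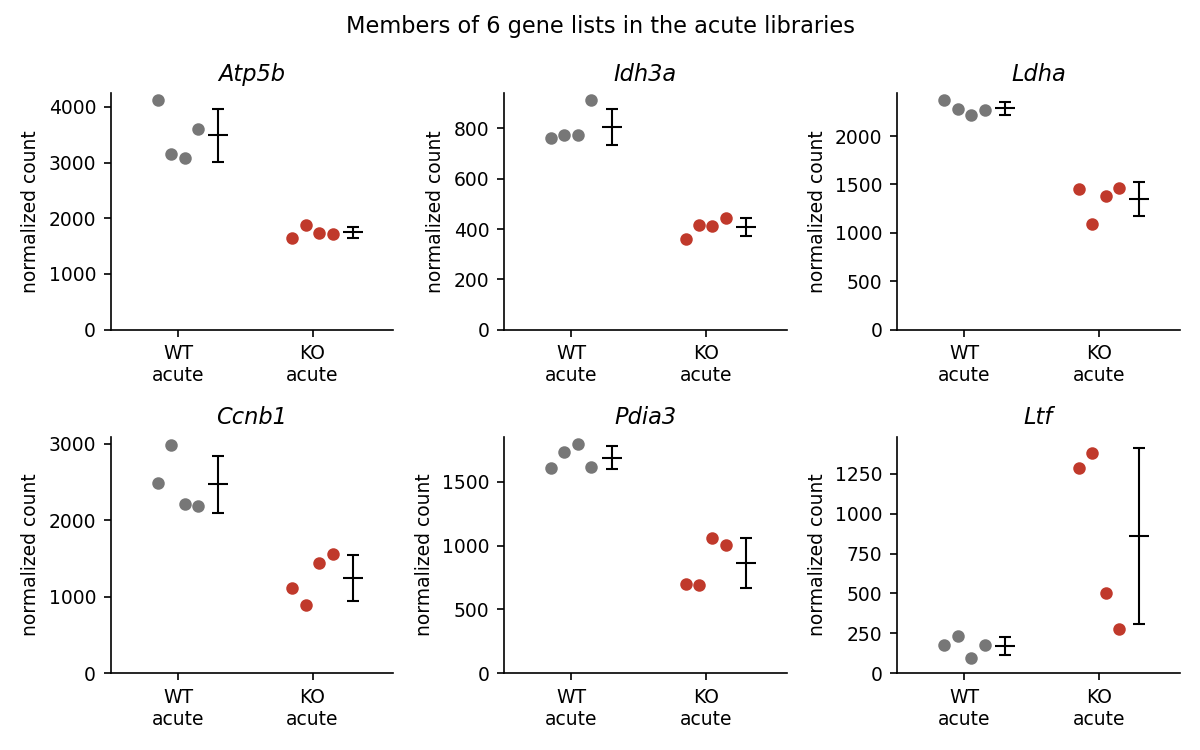
Normalized counts of 6 genes, each from a different gene list, in each acute library (points) with the group mean and SD (bars). Atp5b fell from a mean of 3490 to 1747 and Ltf rose from 172 to 862, with 1288.5 and 1379.1 in KO replicates 1 and 2 and 503.5 and 275.5 in replicates 3 and 4.

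Markers of other spleen cells moved in both directions. All 19 measured markers of neutrophils and their precursors had positive values (median 0.76, adjusted p = 0.000289, and adjusted p = 0.537 with an estimated correlation), and 2 rose, over all genes and when adjusted over the list alone. These were Ltf, lactoferrin, from 172 ± 56.3 (SD, n = 4) to 862 ± 554 (SD, n = 4), log2 2.10 (SE 0.43, adjusted p = 0.00750), and Ngp, neutrophilic granule protein, log2 1.29 (SE 0.32, adjusted p = 0.0185). Itgam, an integrin subunit of myeloid cells, was at 1.13 (adjusted p = 0.0668). All 12 B cell markers were positive (median 0.73, adjusted p = 0.0307, and adjusted p = 0.574 with an estimated correlation) and 0 passed limma's threshold, also when adjusted over the list alone; Cd74, the invariant chain, was at 1.09 (adjusted p = 0.0525) and Blnk, an adaptor, at 0.71 (adjusted p = 0.142), and both had p under 0.05 before adjustment. All 19 erythroid markers were negative (median -0.65, adjusted p = 0.000289, and adjusted p = 0.574 with an estimated correlation), and 1 fell, also when adjusted over the list alone. Slc4a1, the red cell anion exchanger, was at -1.40 (adjusted p = 0.0515) and Hbb-bs, a beta globin, at -1.20 (adjusted p = 0.101). The estimated correlation between the erythroid markers was 0.82, so they moved nearly as 1 measurement. They took 0.118%, 0.237%, 0.0547% and 0.0717% of the counts in KO replicates 1 to 4, against 0.128% to 0.234% in WT. KO replicate 2 was thus above every WT library.

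The KO acute libraries differed among themselves. Mitochondrially encoded genes took 4.8% and 5.3% of the counts in KO acute replicates 1 and 2, and 2.3% and 2.7% in replicates 3 and 4, against 3.5% to 3.7% in WT. Without replicates 1 and 2, Ltf was at 1.18 (adjusted p = 0.0587), Ngp at 0.73 (adjusted p = 0.182) and the neutrophil list at a median of 0.42 (adjusted p = 0.0810). The Ngp call was also lost without WT acute replicate 1 (adjusted p = 0.0508), WT acute replicate 3 (adjusted p = 0.0573) or KO acute replicate 1 (adjusted p = 0.0558). The B cell call was lost without WT acute replicate 2 (adjusted p = 0.138), KO acute replicate 2 (adjusted p = 0.202) or KO acute replicate 4 (adjusted p = 0.0558), and with no filter (0.0854), quantile normalization (0.107), the trend removed (0.0897) or without KO replicates 1 and 2 (0.0810).

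Among single genes, the largest increases past the threshold were those of Sh3pxd2b, a podosome scaffold protein (log2 2.98, SE 0.58), Ltf, Cgref1, a secreted calcium-binding protein (2.02, SE 0.35), Plekhm2, which links lysosomes to kinesin (1.97, SE 0.33), Slfn4, a myeloid schlafen gene (1.75, SE 0.47), and Vasn, vasorin (1.73, SE 0.35). The largest decreases were those of the histone H4 genes Hist1h4m, from 13680 ± 2434 (SD, n = 4) to 3270 ± 1858 (SD, n = 4) normalized counts (log2 -2.25, SE 0.33), and Hist1h4h (-2.18, SE 0.24). Khdrbs2, an RNA-binding protein, was at -2.14 (SE 0.42), Nbdy, a microprotein of mRNA decapping, at -2.04 (SE 0.33), Rpl39, of the large ribosomal subunit, at -1.98 (SE 0.24), and Tmem129, a ubiquitin ligase, at -1.75 (SE 0.31). The highest adjusted p among them was 0.0272, for Slfn4. Reads of H4 histone genes and of Rpl39 can be split with near-identical copies, so their values are uncertain. The Slfn4 call was lost without WT acute replicate 2 (adjusted p = 0.0622), 3 (0.0541) or 4 (0.0774), or without KO acute replicate 1 (0.0794) or 2 (0.0697), and without both of these KO libraries Slfn4 was at 0.60 (adjusted p = 0.170). It was also lost with robust eBayes (0.136), as was that of Ngp (0.0605). With eBayes without a trend the calls of Sh3pxd2b, Ltf, Slfn4, Ngp, Dld, Calr, Rrm1 and Rrm2 were lost (highest adjusted p = 0.119, for Slfn4).

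In all, 1794 of 14184 genes passed the threshold, 650 higher and 1144 lower in KO, and 435 of them changed at least 2-fold (224 higher, 211 lower). For 2695 genes (19.0%) the groups did not overlap, against a chance share of 2.86%. Lower calls made up 63.8% here, 52.7% after quantile normalization (746 higher, 832 lower), 51.8% with the trend over length, GC content and abundance removed (606 higher, 651 lower) and 74.3% without the 2 KO libraries of high mitochondrial share (232 higher, 671 lower). The count was 693 with eBayes without a trend (286 higher, 407 lower), 903 without those 2 KO libraries, 983 without WT acute replicate 4 and 1179 without WT acute replicate 2.

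The other 21 lists were not past the threshold in the acute libraries. Markers of thymocytes and T-ALL had a median of -0.17 (adjusted p = 0.188) and NOTCH1 targets of -0.14 (adjusted p = 0.0978). Lists that use acetyl-CoA had medians of -0.11 for cholesterol synthesis, -0.08 for fatty acid synthesis and 0.21 for histone acetylation enzymes, and fatty acid oxidation was at -0.23 and sterol efflux at -0.04. Of 24 cholesterol synthesis genes 4 fell and 0 rose (7 and 1 when adjusted over the list alone). Of 21 fatty acid synthesis genes 1 fell and 2 rose, also when adjusted over the list alone. Of 28 histone acetylation enzymes 2 fell and 2 rose (2 and 5 when adjusted over the list alone). The medians were 0.02 for MYC targets, -0.12 for p53 targets, -0.12 for the ATF4 stress response, 0.19 for interferon response, -0.05 for oestrogen response, 0.06 for immediate early genes and 0.03 for mitochondrially encoded genes. Of 8 oestrogen response genes 2 rose and 0 fell, over all genes and when adjusted over the list alone. With the trend over length, GC content and abundance removed the mitochondrially encoded list passed, at 0.50 (adjusted p = 0.00411). Among cell markers the medians were 0.59 for dendritic cells, -0.38 for plasma cells, 0.53 for stroma and endothelium, 0.03 for macrophages, -0.08 for platelets, -0.10 for NK cells and 0.11 for mature T cell and migration genes. The median, mean and test differed in sign for MYC targets, oestrogen response, immediate early genes, NK cell markers and sterol efflux.

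In the first wave, genes of the T-ALL program had higher values than in WT as lists, and single genes did not pass the threshold. NOTCH1 targets, the genes driven by the receptor most often activated in T-ALL, had a median of 0.49 over 19 genes, 18 of them positive (camera adjusted p = 5.04e-06, and adjusted p = 0.806 with an estimated correlation). Nrarp, a feedback regulator of NOTCH, was at 1.18 (SE 0.43), Tspan2, a tetraspanin, at 0.91 (SE 0.38), and Ptcra, the pre-T-cell receptor alpha chain, at 0.74 (SE 0.33). Markers of thymocytes and T-ALL had a median of 0.21 over 24 genes (adjusted p = 0.00132), with the recombinase genes Rag2 at 1.35 (SE 0.49) and Rag1 at 0.94 (SE 0.32) and the T-lineage factor Bcl11b at 0.92 (SE 0.30). Genes of G2 and mitosis were lower (27 genes, median -0.23, adjusted p = 0.00157), with Dlgap5, a spindle protein, at -0.65 (SE 0.25), Cenpf, of the kinetochore, at -0.63 (SE 0.21) and Aurkb, a mitotic kinase, at -0.61 (SE 0.20). Neutrophil markers were lower (14 genes, median -0.95, adjusted p = 0.0107), with the granule protein genes Camp at -1.83 (SE 0.83) and Lcn2 at -1.55, and Elane, neutrophil elastase, at a mean of 0.409 ± 0.708 (SD, n = 3) against 56.2 ± 70.1 (SD, n = 4) normalized counts. With an estimated correlation all 4 lists had adjusted p = 0.806. Of these lists 0 members passed limma's threshold, also when adjusted over the list alone, and the named members had adjusted p of 0.617 to 0.623.

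In all, 0 of 14286 genes passed limma's threshold in the first wave and 1146 had an unadjusted p under 0.05. The groups did not overlap for 1143 genes (8%), against a chance share of 5.71%. Among WT survival libraries, replicates 1 and 2 stood apart on the first principal component (78.6 and 67.2, against -18.8 and 4.2 for replicates 3 and 4), and without both the NOTCH1 list was at 0.09 (adjusted p = 0.465), the thymocyte and T-ALL list was not called (adjusted p = 0.385) and neutrophil markers were at 0.09 (adjusted p = 0.780). The G2 and mitosis call was lost without first-wave replicate 1 (adjusted p = 0.131) and the neutrophil call without first-wave replicate 2 (adjusted p = 0.102) or WT survival replicate 1 (adjusted p = 0.168). The median, mean or test differed in sign for immediate early genes, fatty acid synthesis, fatty acid oxidation and acetyl-CoA supply, none of them called.

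In the second wave, Ccnd1, the cyclin D1 gene of the G1 phase (chromosome 7, 144929931 to 144939925), rose from 57.9 ± 18.8 (SD, n = 4) in WT to 539 ± 201 (SD, n = 3) normalized counts (log2 3.18, SE 0.36, adjusted p = 0.00188). H2-Q7, an MHC class I gene (chromosome 17, 35439155 to 35443773), fell from 1168 ± 236 (SD, n = 4) to 204 ± 16.1 (SD, n = 3) (log2 -2.49, SE 0.20, adjusted p = 7.00e-05). The adhesion receptor gene Adgrg5 rose by 2.87 (SE 0.43) and the receptor gene Gpr83 by 2.45 (SE 0.34), and Pnn, a splicing factor, was at 0.96 (SE 0.14). Syt14, a synaptotagmin, fell by 2.06 (SE 0.25), from 687 ± 39.9 (SD, n = 4) to 172 ± 71.6 (SD, n = 3). Ndufaf4, which assembles respiratory complex I, was at 1.30, Zfp704, a zinc finger protein, at 0.89, Ddx60, an antiviral helicase, at -2.87, Bach2, a transcriptional repressor, at -2.74, and Trim30d, a TRIM family gene, at -2.13. Reads of H2-Q7 and Trim30d can be split with near-identical family members, so their values are uncertain.

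**Figure D3:**
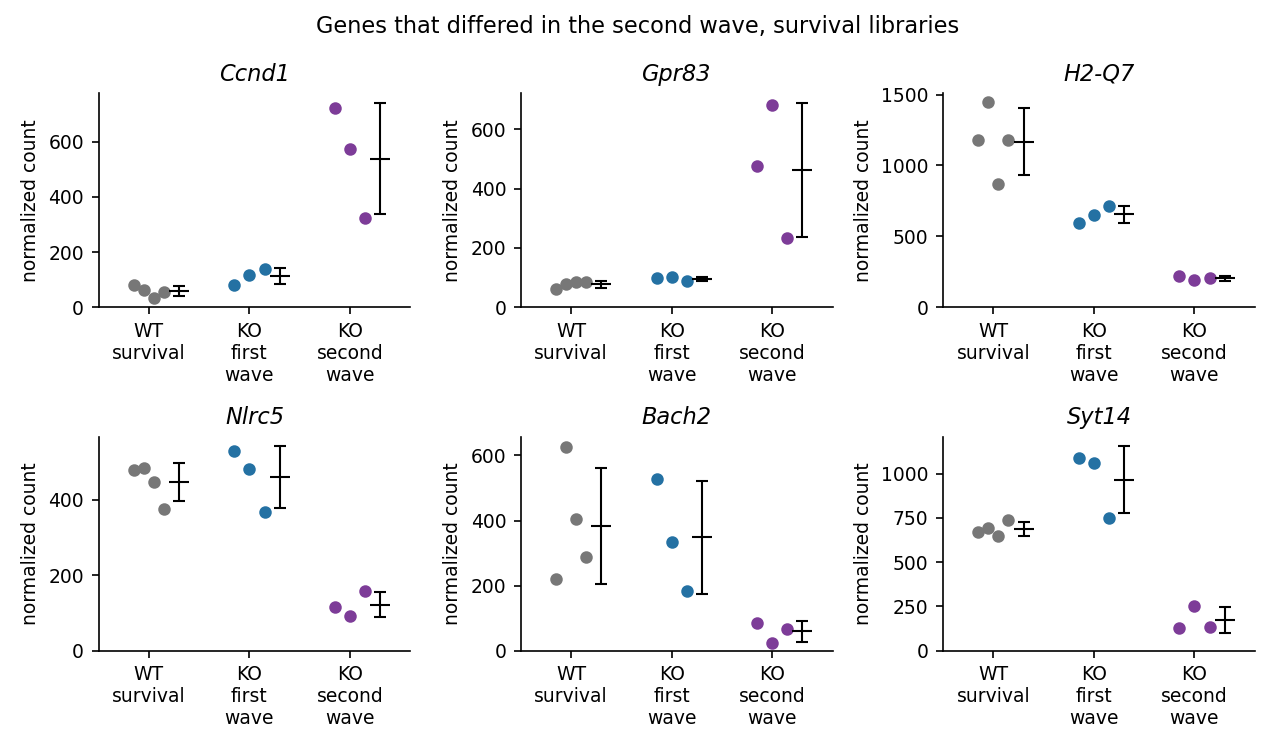
Normalized counts of 6 genes named for the second wave or the comparison of the waves, in each survival library (points) with the group mean and SD (bars). Ccnd1 averages 539 in the second wave against 57.9 in WT and 112 in the first wave, and H2-Q7 averages 204 against 1168 in WT and 654 in the first wave.

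Gene lists of B cells and of interferon response were lower in the second wave. Of 11 B cell markers 1 fell, and 3 when adjusted over the list alone (median -0.95, adjusted p = 0.000185, and adjusted p = 0.0734 with an estimated correlation). Pax5, the B-lineage factor, fell by 4.81 (SE 0.81) to 1.68 ± 1.60 (SD, n = 3) from 68.3 ± 29.6 (SD, n = 4) normalized counts, and Ms4a1, a B cell surface protein, was at -1.29. Of 28 interferon response genes 0 passed limma's threshold and 5 fell when adjusted over the list alone (median -0.44, adjusted p = 0.00110, and adjusted p = 0.0734 with an estimated correlation). Gbp2, a guanylate-binding protein, was at -1.27 (SE 0.26), Rtp4 at -1.39 (SE 0.37) and the transcription factor gene Stat2 at -1.09 (SE 0.32), all 3 with unadjusted p under 0.05. Genes of G2 and mitosis had a median of -0.21 with 0 called, also when adjusted over the list alone (adjusted p = 0.0360, and adjusted p = 0.607 with an estimated correlation), with Cenpf at -0.79, Dlgap5 at -0.64 and Cenpe, a kinetochore motor, at -0.44.

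Lists of growth and amino acid supply were higher in the second wave. MYC targets and ribosome biogenesis had a median of 0.32 over 26 genes (adjusted p = 0.000185, and adjusted p = 0.380 with an estimated correlation), with 0 genes called and 1 when adjusted over the list alone. Gnl3, nucleostemin, was at 0.66, Tfrc, the transferrin receptor, at 0.90 and Utp20, of ribosomal RNA processing, at 0.47. The ATF4 stress response list was at 0.28 over 22 genes (adjusted p = 0.0141, and adjusted p = 0.446 with an estimated correlation), with 0 called and 4 higher when adjusted over the list alone. Aldh18a1, of proline synthesis, was at 1.48, Slc7a1, a cationic amino acid transporter, at 0.60 and Cars, a cysteinyl-tRNA synthetase, at 0.84. Glycolysis was at 0.14 over 19 genes (adjusted p = 0.0143, and adjusted p = 0.607 with an estimated correlation), with 0 called and 2 higher when adjusted over the list alone. Hk2, a hexokinase, was at 2.32, Slc2a3, a glucose transporter, at 0.86 and Pgam1, a phosphoglycerate mutase, at 0.54. NOTCH1 targets were at 0.31 (adjusted p = 0.0575). The median, mean or test differed in sign for mature T cell, stromal, and thymocyte and T-ALL markers, none of them called.

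In all, 32 of 14286 genes passed the threshold in the second wave, 7 higher and 25 lower, and 1857 had an unadjusted p under 0.05. The groups did not overlap for 1380 genes (9.66%), against a chance share of 5.71%. Second-wave replicate 1 also stood apart, at -73.2 on the first principal component against -9.9 and -16.5 for replicates 2 and 3. On the second component it was at -83.2, against 10.1 and 21.6. The count was 140 without WT survival replicate 3, with 76 higher and 64 lower, so that lower calls no longer prevailed. It was 61 without second-wave replicate 3, 15 without WT survival replicate 2, 19 without WT survival replicate 1, and 21 without first-wave replicate 1 or 2. It was 14 without both WT libraries that stood apart, where Adgrg5 and Gpr83 had adjusted p of 0.0982 and 0.0632 and the calls of Pax5, Ndufaf4, Zfp704, Bach2 and Ddx60 were lost too (highest 0.255, for Pax5). Calls lost without 1 library were those of Bach2 (without first-wave replicate 2, second-wave replicate 2, or WT survival replicate 2 or 4, highest adjusted p = 0.0923), Ddx60 (without second-wave replicate 1, or WT survival replicate 1 or 2, highest 0.0852) and Pax5 (without second-wave replicate 1, or WT survival replicate 1, 2 or 4, highest 0.116). Ndufaf4 lost its call without any library but second-wave replicate 2 or WT survival replicate 3 (highest adjusted p = 0.140), and Trim30d without any but WT survival replicate 1 or 3 (highest 0.0897). Zfp704 lost it without any but first-wave replicate 1, second-wave replicate 3 or WT survival replicate 3 (highest 0.143). With eBayes without a trend the calls of Pax5, Ndufaf4, Pnn, Zfp704, Trim30d, Bach2 and Ddx60 were lost (highest adjusted p = 0.190, for Zfp704). With only the groups compared in the fit those of Ndufaf4, Pnn, Zfp704, Trim30d, Bach2 and Ddx60 were lost (highest 0.148, for Ndufaf4).

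The list of G2 and mitosis lost its second-wave call without second-wave replicate 3 (adjusted p = 0.361), WT survival replicate 2 (0.0990) or WT survival replicate 3 (0.106), or without both WT libraries that stood apart (0.152). Glycolysis lost it without second-wave replicate 1 (0.156) or WT survival replicate 4 (0.160). With the replicate number as a block, the KO and WT estimates equal those without WT survival replicate 4, the only survival library of that number. In that fit the calls of glycolysis (median 0.06, adjusted p = 0.158) and of the ATF4 stress response (0.22, adjusted p = 0.0510) were lost. So were those of Pax5, Ndufaf4, Zfp704, Trim30d and Bach2 (highest adjusted p = 0.109, for Trim30d).

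The direct test between the waves asks whether the KO leukemias of the second wave differed from those of the first. Ccnd1 and Gpr83 were higher in the second wave, by 2.21 (SE 0.39, adjusted p = 0.0444) and 2.13 (SE 0.36, adjusted p = 0.0439). Nlrc5, the transactivator of MHC class I genes, fell by 1.92 (SE 0.26, adjusted p = 0.00912), from 461 ± 83.3 (SD, n = 3) to 122 ± 32.8 (SD, n = 3) normalized counts. Syt14 fell by 2.54 (SE 0.26, adjusted p = 0.00200) and Tubb2b, a tubulin, fell from 849 ± 105 (SD, n = 3) to 219 ± 73.5 (SD, n = 3) (adjusted p = 0.00735). Cd200, a surface glycoprotein, was at -3.84, Trim30d at -2.54 and Apol7e, an apolipoprotein L family gene, at -2.31, with adjusted p of 0.0407 to 0.0439. Reads of Trim30d and Apol7e can be split with near-identical family members, so their values are uncertain.

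As lists, markers of thymocytes and T-ALL were lower in the second wave (24 genes, median -0.29, adjusted p = 7.96e-05, and adjusted p = 0.327 with an estimated correlation), with 0 called and 1 lower when adjusted over the list alone. Dntt, the terminal transferase, was at -0.94 (SE 0.22), Tcf12, an E protein, at -0.43 and Cd8a, a T-cell coreceptor, at -0.58. B cell markers were at -0.95 (11 genes, adjusted p = 0.00168, and adjusted p = 0.120 with an estimated correlation), with Ms4a1 at -1.34, Pax5 at -2.51 and Cd22 at -2.27, and plasma cell markers at -0.38 (6 genes, adjusted p = 0.0194, and adjusted p = 0.212 with an estimated correlation), with Jchain, the immunoglobulin joining chain, at -1.42, Tnfrsf13b at -0.54 and Prdm1 at -0.86. Interferon response was at -0.35 (28 genes, adjusted p = 0.00654, and adjusted p = 0.120 with an estimated correlation), where Gbp2 fell by 1.64 (adjusted p = 0.0444), over all genes and when adjusted over the list alone, and Rtp4 was at -1.15. When adjusted over the list alone, 0 B cell and 1 plasma cell marker were lower.

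Higher in the second wave were MYC targets (26 genes, median 0.24, adjusted p = 0.00213, and adjusted p = 0.327 with an estimated correlation), with Cad, of pyrimidine synthesis, at 0.84, Gnl3 at 0.41 and Nop56, a nucleolar protein, at -0.38. The oestrogen response list was at 0.32 (9 genes, adjusted p = 0.00213, and adjusted p = 0.120 with an estimated correlation), with Ccnd1 called, 2 genes higher when adjusted over the list alone, and Nrip1, a corepressor of nuclear receptors, at 0.84 and Rara, a retinoic acid receptor, at 1.32. S phase was at 0.21 (26 genes, adjusted p = 0.00411, and adjusted p = 0.581 with an estimated correlation), with the replication genes Cdc6 at 0.41, Mcm3 at 0.38 and Mcm5 at 0.35. The ATF4 stress response was at 0.30 (22 genes, adjusted p = 0.00887, and adjusted p = 0.327 with an estimated correlation), with Aldh18a1 at 1.16, Slc7a1 at 0.61 and Slc7a5, an amino acid transporter, at 0.78. Platelet markers were at 0.78 (5 genes, adjusted p = 0.0194, and adjusted p = 0.399 with an estimated correlation), with the integrin genes Itga2b at 2.76 and Itgb3 at 1.27 and the collagen receptor gene Gp6 at 0.78. In these 5 lists, the numbers higher when adjusted over the list alone were 0 for MYC targets, S phase and ATF4 and 1 for platelets.

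In all, 17 of 14286 genes passed the threshold between the waves, 2 higher and 15 lower, and 906 had an unadjusted p under 0.05. The groups did not overlap for 1942 genes (13.6%), against a chance share of 10%. The count was 1 without first-wave replicate 1 or 2, 10 without first-wave replicate 3, 6 without second-wave replicate 1, 38 without second-wave replicate 3, 4 without WT survival replicate 2, and 8 without WT survival replicate 3 or 4. With eBayes without a trend it was 1. Without first-wave replicate 1 or 2, adjusted p was 0.107 in both fits for Nlrc5, 0.0614 and 0.0843 for Tubb2b, and 0.319 and 0.248 for Ccnd1. Gbp2 lost its call without any library but second-wave replicate 1 (highest adjusted p = 0.306), Gpr83 and Cd200 without any but second-wave replicate 3 or WT survival replicate 1 (highest 0.248 and 0.234). Apol7e lost it without any but second-wave replicate 2 or WT survival replicate 1 (highest 0.291). Trim30d lost it without any but first-wave replicate 3 or WT survival replicate 1 or 4 (highest 0.259), and Ccnd1 without any but second-wave replicate 3 or WT survival replicate 1 or 3. With the replicate number as a block the count was 2 and the calls of Gbp2, Ccnd1, Gpr83, Nlrc5, Apol7e, Trim30d and Cd200 were lost (highest adjusted p = 0.126, for Gbp2). Of the 9 named genes past the threshold, 0 kept their call in every alternative, and Syt14 kept it whichever library was left out.

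Of the lists between the waves, oestrogen response lost its call without second-wave replicate 1 (adjusted p = 0.0509) and interferon response without second-wave replicate 3 (0.0741). S phase lost it without first-wave replicate 2 (0.383) or second-wave replicate 1 (0.0522). Plasma cell and platelet markers lost it without first-wave replicate 1 (0.143 for both) or second-wave replicate 1 (0.0509 and 0.175), and platelet markers also with no filter (0.0503). The median, mean or test differed in sign for immediate early genes, glycolysis, mature T cell markers and sterol efflux, none of them called.

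Over both waves together, 3 of 14286 genes differed from WT, and 1838 had an unadjusted p under 0.05. Ccnd1 was higher, by 2.08 (SE 0.31, adjusted p = 0.0379), and Acly and H2-Q7 were lower, at -1.39 (SE 0.14, adjusted p = 0.000798) and -1.65 (SE 0.17, adjusted p = 0.000798). The groups did not overlap for 303 genes (2.12%), against a chance share of 0.952%. The count was 155 without WT survival replicate 3 (96 higher, 59 lower) and 5 without second-wave replicate 3 (3 higher, 2 lower), so that higher calls prevailed in both. Ccnd1 lost its call without any library but second-wave replicate 3 or WT survival replicate 1 or 3 (highest adjusted p = 0.179). It also lost it with the replicate number as a block (0.137) and with eBayes without a trend (0.362).

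The genes called in the acute comparison were followed as lists in the survival libraries. The 1144 genes lower in acute KO had positive medians in the first wave (0.17, adjusted p = 1.05e-10) and the second wave (0.16, adjusted p = 5.90e-08), and 24.0% and 29.2% of them had the acute sign. The 642 tested genes of those higher in acute KO had medians of -0.21 (adjusted p = 2.17e-07) and -0.22 (adjusted p = 1.60e-06), and 31.3% and 28.7% had the acute sign. With an estimated correlation the adjusted p of all 4 tests was 0.330. Both waves were compared with the same 4 WT libraries, so these are not independent. In the first wave the medians were -0.33 for the higher genes without WT survival replicate 3 and 0.11 for the lower genes without WT survival replicate 4. In the second wave the higher genes were at -0.11 without second-wave replicate 1 and -0.36 without WT survival replicate 3, and the lower genes at 0.10 without second-wave replicate 1 and 0.09 without WT survival replicate 4. Between the waves neither list passed (adjusted p = 0.886 for both), but without second-wave replicate 1 both did (0.10 for higher and -0.06 for lower genes, adjusted p = 0.0204 and 0.0153), and without second-wave replicate 3 the lower genes did with the other sign (0.06, adjusted p = 0.0297).

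**Figure D4:**
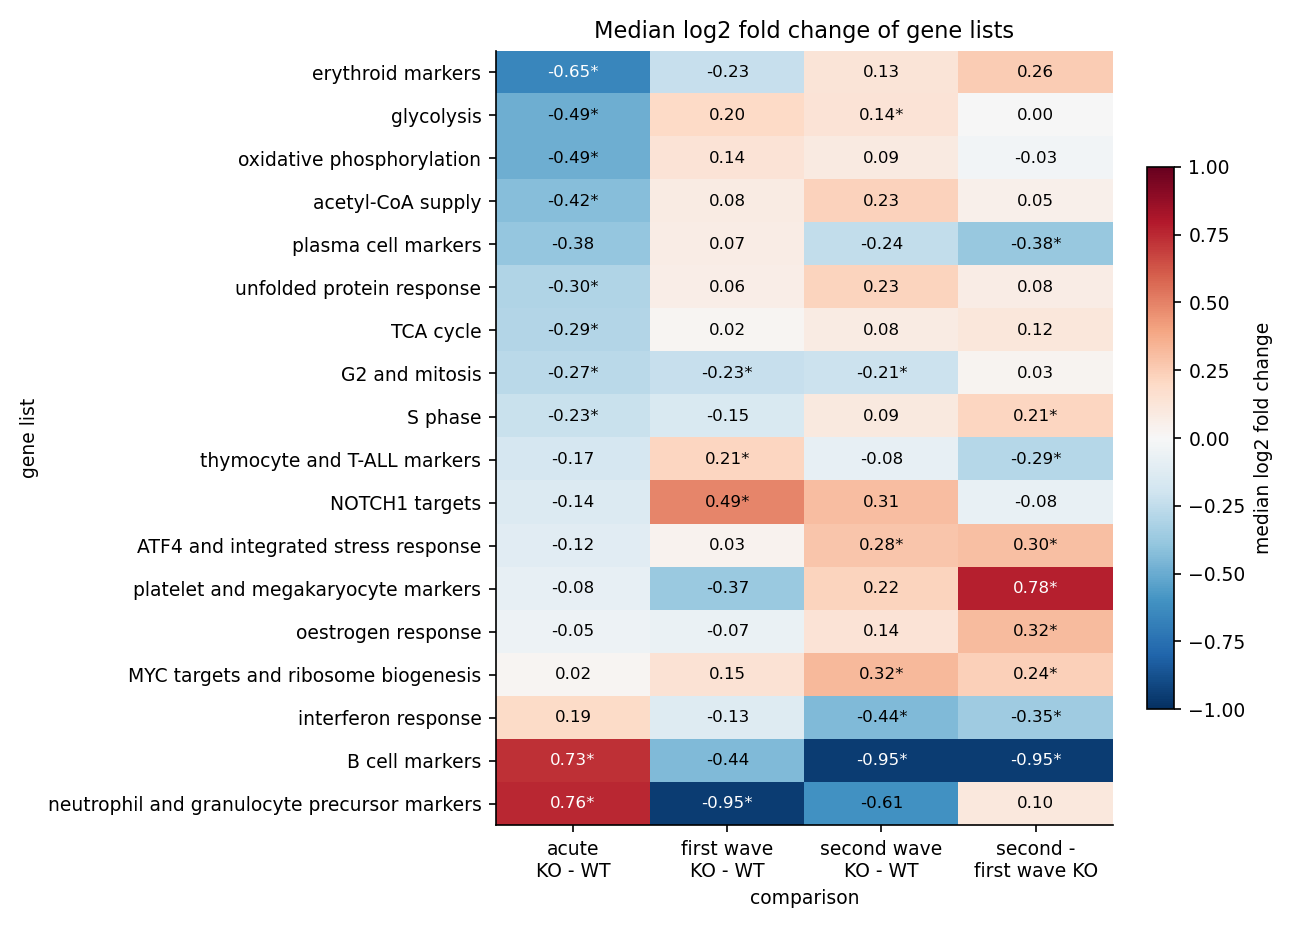
Median log2 fold change (colour and number) of the gene lists past the threshold in at least 1 of 4 comparisons; an asterisk marks an adjusted p under 0.05 at the preset correlation. Oxidative phosphorylation is at -0.49 in the acute comparison and at 0.14 and 0.09 in the first and second waves, and with an estimated correlation 0 lists passed in any comparison.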

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

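The tests of the oxidative phosphorylation list, of the NOTCH1 list against 2 WT survival libraries, and of non-leukemic cells behind the MHC class I genes were chosen after the results were seen, as was the MHC class I list itself. The test of granulocyte dilution, the summed class I counts and the splits of the libraries were set before their results were seen.

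In acute KO the oxidative phosphorylation list was lower, with a median of -0.49. Random lists matched on transcript length, GC content and abundance had a median of -0.18, and the list lay at percentile 0.02 of 10000 of them. With these trends removed it was at -0.36 (camera adjusted p = 8.47e-05 at the preset correlation). The trends thus gave part of the median of these genes and not all of it. Whether the rest exceeds the spread between libraries is not decided. The random genes were drawn singly, which leaves out the correlation within the list, and an estimated correlation was not used with the trends removed. A lower share of leukemic T cells would lower T-ALL markers at least as much, and their median was higher by 0.319 (bootstrap SE 0.129, over genes and not libraries). But 6 of these markers fell and 3 rose. T-cell receptor genes, chosen after their values were seen, were lower with no overlap. Trbc2 was at 2497 to 3523 normalized counts in KO and 3870 to 4348 in WT. All Trbv segments together were at 1256 to 1731 and 2091 to 2866. A lower share of leukemic T cells therefore stays open. The acute groups also differed in the make-up of their libraries with no overlap: the lower quartile of the values was 11.4 to 13.1 in KO and 9.4 to 9.9 in WT, and the normalized totals were 7.07 to 7.26 M and 7.64 to 8.03 M. With the distributions made equal by quantile normalization the list was still past the threshold, at -0.51, but a difference in RNA or library quality between the groups was not tested and stays open. An effect of losing Acly stays open, and so does an effect of tamoxifen, which all KO and no WT mice received. With an estimated correlation the list had adjusted p = 0.262.

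In the first wave the NOTCH1 target list was higher at the preset correlation, with a median of 0.49, but not with an estimated correlation (adjusted p = 0.806). Against the 2 WT libraries that did not stand apart it was 0.0893 (adjusted p = 0.465), so the 2 WT libraries that did may be the source of the difference. Dilution of WT libraries by granulocyte precursors is argued against, since neutrophil markers took at most 0.0263% of all counts in a WT survival library. What set these 2 libraries apart was not tested, and a biological difference of the first wave stays open. The 2 other WT libraries are no plain reference either. In replicate 3 the T-cell receptor segment Trbv5 took 55.8% of Trbv segment counts, and replicate 4 had the highest lower quartile of the survival libraries, 10.9. Which WT libraries are unusual therefore stays open too.

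In the second wave the MHC class I presentation list of 20 genes had a median of -0.27. It holds H2-Q7 and Nlrc5, whose fall led to it, so it is no test of the pattern. Of its genes 15 had negative values and 5 positive ones. Past the threshold 5 were lower: H2-Q7, H2-Q6, Nlrc5, H2-D1 and H2-K1. Fewer non-leukemic cells cannot be told apart. The pooled markers of other cell types were at -0.12, a difference of 0.155 (bootstrap SE 0.243) from the list, but their lists went both ways, so the pooled median decides nothing. A further test, written after that result, asked whether those cell types fell alike: their list medians spanned 1.21, from -0.95 for B cells to 0.26 for macrophages, against a median span of 0.927 with genes reassigned among lists (permutation p = 0.170), which does not decide. Reads moved between near-identical class I genes cannot be told apart either. The summed counts of 18 class I genes, some not in the list, gave a log2 ratio of -0.304, between the bounds set for the test. The sums were 81.0% of WT in the second wave and 97.7% in the first. Together the class I genes outside the list were higher than in WT in the first and the second wave, so the sums can hide lower values of listed genes. In the first wave the list had a median of -0.17, with 12 negative and 8 positive values, and 0 genes passed the threshold. H2-Q7 was at -0.82 there, with no overlap with WT (limma adjusted p = 0.617). Lower values are thus not shown to be particular to the second wave. A biological difference of the second wave stays open; whether the leukemia cells themselves lost class I expression was not tested, and RNA of sorted leukemia cells would test it.

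Other splits of the same libraries were also counted. In the acute comparison the real split gave 1794 genes and the others at most 1, so 1 of 35 splits gave as many. That is the smallest share that 35 splits allow. It sets the 2 groups apart but does not tell by what, since their libraries also differed in make-up. In the first wave the splits decide nothing: with a real count of 0 all 35 of 35 must give as many, and the highest other was 2. In the second wave chance cannot be excluded: the real count was 32, 2 of 35 splits gave as many, and the highest other was 217, in the split of WT survival replicates 1, 2 and 4 from the rest, which points to a structure of the samples. Between the waves the real count was 17 and the highest other 2 (1 of 10 splits gave as many), and 10 splits are too few for a share under 0.05. Over both waves the real count was 3 and the highest other 22; 4 of 100 drawn splits gave as many, a share under 0.05, but the highest, with WT survival replicates 1 and 2 together, again points to a structure of the samples, so a count of 3 is not set apart from it.

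A single library lay far from the others of its group in 14 of 254 tests, and chance gives about 1 in 20. The test, Dixon's, used the critical value for 4 libraries, so it gives no result on the waves, which had 3 libraries each. Estimated reads were 8.7 M in KO acute replicate 3 and 7.9 M in WT survival replicate 1. Among genes these were Dld (881.89) and Rpl39 (2679.5) in WT acute replicate 1, Idh3a (910.8) in WT acute replicate 4, Vasn (70.621) in WT acute replicate 2 and Tmem129 (114.09) in KO acute replicate 1. In the survival libraries they were Itgb3 (170.78) in WT replicate 4 and Pgam1 (676.09) in WT replicate 3. Among mean log2 values of lists they were fatty acid oxidation in WT acute replicate 1 (7.03), p53 targets (7.27) and mature T cell genes (5.95) in WT acute replicate 4, histone acetylation enzymes in KO acute replicate 1 (8.80), and mitochondrially encoded genes in WT survival replicate 4 (13.16).

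The second wave differed from the first by a direct test in 17 genes, among them Gbp2 (-1.64), Ccnd1 (2.21), Gpr83 (2.13), Nlrc5 (-1.92), Tubb2b (-2.00), Apol7e (-2.31), Syt14 (-2.54), Trim30d (-2.54) and Cd200 (-3.84). List medians that differed were those of thymocyte and T-ALL markers (-0.29), B cells (-0.95), MYC targets (0.24), oestrogen response (0.32), S phase (0.21), interferon response (-0.35), ATF4 (0.30), plasma cells (-0.38) and platelets (0.78). These lists passed at the preset correlation, and with an estimated correlation 0 did (smallest adjusted p = 0.120). The count of genes was 1 without first-wave replicate 1 or 2, 10 without first-wave replicate 3, 6 without second-wave replicate 1, 38 without second-wave replicate 3, 4 without WT survival replicate 2 and 8 without WT survival replicate 3 or 4, and of the 9 genes named here Syt14 alone kept its call whichever library was left out. The S phase call was lost without first-wave replicate 2 (adjusted p = 0.383) or second-wave replicate 1 (0.0522), the oestrogen response call without second-wave replicate 1 (0.0509) and the interferon response call without second-wave replicate 3 (0.0741). The plasma cell and platelet calls were lost without first-wave replicate 1 (0.143 for both) or second-wave replicate 1 (0.0509 and 0.175).

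For some results every library of the acute and of a survival comparison moved in opposite directions, and these differences were not tested. Lower in acute KO and higher in survival KO were Gpr83 (-0.98 acute, 0.32 first wave, 2.45 second wave), Pnn (-0.20, 0.51, 0.96) and Tmem129 (-1.75, 1.10, 1.00). In the second wave alone these were Ldha (-0.77, then 0.33), Nrarp (-0.39, then 1.35) and the mean over all genes of the glycolysis list in the tables, low ones included (-0.36, then 0.34, against 0.38 over the 19 genes tested), and in the first wave alone Pdia3 (-0.99, then 0.26). Higher in acute KO and lower in survival KO were Stat2 (0.86, then -0.90 and -1.09), and in the second wave Slfn4 (1.75, then -1.36) and Trim30d (0.62, then -2.13).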

How the results depend on the processing

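The removal of trends and the fits without 2 KO acute or 2 WT survival libraries were chosen after the data were seen. Acly and the named genes past the threshold kept their direction, but the prevailing direction of the counts turned without WT survival replicate 3 (second wave 76 higher and 64 lower, both waves 96 and 59), and over both waves also without second-wave replicate 3 or the 2 WT libraries (3 and 2 in each). With an estimated correlation, camera called 0 lists in each of the 4 comparisons and 0 of the acute call tests in the survival libraries. The acute count was 693 with eBayes without a trend and 903 without the 2 KO libraries. In the first wave limma's count was 1 with pseudocount 5, with no filter, with a mean of at least 50, with quantile normalization and with robust eBayes, against 0 in the report (1146 genes at unadjusted p under 0.05), and 3 without the 2 WT libraries. There Acly passed at -1.22 in the first 4 of these (adjusted p = 0.0483, 0.0440, 0.0424 and 0.0459). The second-wave count was 14 with eBayes without a trend, 14 without the 2 WT libraries and 13 with only the groups compared, and its lists numbered 11 with no filter and 11 without the 2 WT libraries. Between the waves the count was 1 without a trend, 2 with the replicate number as a block and 34 without the 2 WT libraries, and over both waves it was 5 without them. The cause was not tested. With each library left out, the acute count ranged from 983 to 1634, the first-wave count from 0 to 3, its Acly value from -1.29 to -1.15 and its lists from 3 to 8, the second-wave count from 15 to 140, the wave count from 1 to 38 and its lists from 5 to 13, and the count over both waves from 2 to 155. Of the named genes past the threshold, 24 of 34 acute, 3 of 13 second-wave, 0 of 9 wave and 1 of 2 pooled genes kept their call in every alternative. Replicate numbers did not pair the libraries: the correlations of same-numbered libraries were -0.029 to 0.0065 in the acute and -0.029 to 0.0946 in the survival table, and the block gave 1391 acute, 0 first-wave, 34 second-wave and 2 pooled genes. In the survival fit the block takes up WT survival replicate 4, so it is not separate from the fit without that library. The edgeR and DESeq2 alternatives were not run, since whole reads were not recovered. Values near the smallest step, such as those of Elane and Pax5 in KO survival libraries, rest on few reads.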

Other observations

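The gene classes and T-cell receptor segments below, and the test of polyclonal T cells, were chosen after their values were seen, and the test of the acute calls against 2 WT libraries was set before its result. Of 62 histone genes in the acute libraries 28 fell and 0 rose (median -0.76), of 77 ribosomal protein genes 25 fell and 1 rose (median -0.29), and of 734 processed pseudogenes 62 rose and 16 fell (median 0.33). Fold changes of 13123 protein-coding genes correlated with transcript length (rho = 0.14), GC content (0.20) and abundance (-0.27). The lower quartile of the values was higher in every acute KO library (11.4 to 13.1) than in WT (9.4 to 9.9) and the normalized total lower (7.07 to 7.26 M against 7.64 to 8.03 M), so library quality as the source of these class changes is not excluded. In the survival comparisons limma called 0 genes of these classes, with histone medians of -0.06 in the first wave, -0.02 in the second and 0.24 between the waves (44 of 62 positive). In the same order the medians were 0.02, -0.08 and -0.08 for ribosomal protein genes and -0.19, -0.26 and -0.08 for processed pseudogenes.

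The use of T-cell receptor beta variable segments differed between survival libraries. Trbv26 took 55.5% to 66.7% of segment counts in WT acute, 32.8% to 55.8% in KO acute and 65.4% to 74.4% in first-wave libraries. In KO acute replicate 2, Trbv2 took 33.0%, against 12.6% to 14.4% in the other KO acute libraries. In WT survival replicates 1 to 4 Trbv26 took 73.0%, 74.0%, 21.8% and 60.7%, and in replicate 3 Trbv5 took 55.8%. In second-wave replicates 1 to 3 Trbv26 took 26.7%, 53.4% and 1.3%, beside Trbv1 at 34.1% and Trbv17 at 27.7% in replicate 1, Trbv19 at 11.5% in replicate 2 and Trbv1 at 95.0% in replicate 3. Residual polyclonal T cells in WT survival replicate 3 are argued against, since a single segment, Trbv5, took 93.5% of the counts outside Trbv26, Trbv2 and Trbv1. A hypothesis left open is that this library and second-wave libraries hold other leukemic clones, which may differ in expression for reasons other than Acly; without WT survival replicate 3 the second-wave count was 140, against 32 with it.

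Genes lower in acute KO had positive medians in survival KO. The 2 WT survival libraries that stood apart do not account for all of these medians, which against the 2 others were 0.146 in the first wave and 0.137 in the second. Those of the genes higher in acute KO moved further, from -0.21 to -0.12 and from -0.22 to -0.14, and stayed past the threshold at the preset correlation (adjusted p = 0.000182 and 0.000645). With an estimated correlation neither list passed in either wave against all WT libraries (adjusted p = 0.330 in all 4 tests), so the pattern itself is uncertain. The signs rest on the same WT libraries in both waves. WT survival replicate 4, which did not stand apart, had a lower quartile of 10.9 and a normalized total of 9.19 M. The other survival libraries had 7.1 to 9.9 and 9.70 to 10.39 M. Without replicate 4 the genes lower in acute KO had medians of 0.11 in the first wave and 0.09 in the second. A difference in library quality behind the pattern was not tested and stays open.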
